A study of Mus musculus with 2 samples.

How the data were processed

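DNase-seq was carried out on kidney tissue of 2 female B6CASTF1/J mice aged 2 months, per the labels. B6CASTF1/J is the first-generation hybrid of the inbred strains C57BL/6J and CAST/EiJ. In DNase-seq, nuclei are digested lightly with DNase I and the cut ends are sequenced, so that regions of accessible chromatin collect many cuts and bases shielded by a bound protein collect few. The labels give each library its own biological replicate number and animal number (replicate 1 is animal 6 and replicate 2 is animal 5), and both carry the same donor entry. They were treated as libraries of separate animals in 1 group. The labels give no second group, so no contrast between conditions was made and each value describes these libraries.

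Per the labels and the text file deposited with each library, peaks and footprints were called separately in each library from its filtered alignments to mm10, without pooling the replicates. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. Each library has a pair of peak lists in which every peak carries a signal value scaled by the authors to the library's depth. All deposited signal values were whole multiples of 1 step per library, within a tolerance of 0.05 of a step, the step being 0.00350 in replicate 1 and 0.00182 in replicate 2. The scale of the signal is not given in the sources used here. If a step stands for 1 cut in each library, the depth of replicate 2 was 1.92 times that of replicate 1, and no absolute depth was derived. A further deposited file per library lists the false discovery rate (FDR, an adjusted p-value or q-value) of the cut rate along the genome, where it is below 0.05. In both libraries, the lowest FDR inside each peak of the shorter list was under 0.001 and that inside each peak of the longer list was under 0.05. The shorter list is called stricter here and the longer list looser. The stricter list was the main list, since the plan called for the narrower of the 2 lists and the lists differ in stringency, not in kind. The looser list served as an alternative and in tests of overlap. The footprint files deposited by the authors give 1 constant FDR of 0.01 and no value per footprint.

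Positions were set against GENCODE gene records and genome sequence of GRCm38, the assembly that mm10 names. The gene start was the 5′ end of the gene record of 21938 protein-coding genes, so other annotated starts of a gene were not searched. A gene was given a promoter peak where a peak lay within 1 kb of that start, and its promoter signal was the highest signal of such a peak. Distal peaks were counted in the gene body and 20 kb on either side, leaving out peaks within 1 kb of any protein-coding gene start, and were given per 10 kb.

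Overlap of peaks or footprints meant at least 1 shared base (bedtools 2.31.1). The overlap expected by chance was taken from 100 circular shifts along each chromosome. Promoter peaks of a gene list were compared with those of all other protein-coding genes by Fisher's exact test, two-sided, in each library. Distal peaks were compared by a two-sided permutation test of the list's median against 10000 random lists of the same size, matched on decile of locus length, for which the smallest p is 0.0002. Both were adjusted by the Benjamini-Hochberg method over 23 lists within a library, and a list was called where the adjusted p was below 0.05 in both libraries in the same direction. Genes are not independent replicates, so these p-values describe the lists in these libraries and not a population of animals. The 23 lists, of 361 genes, cover 9 cell types of the kidney, 4 tissues that dissection could carry along (urothelium, adipocytes, adrenal gland, erythroid cells), 4 tissues absent from the sample (liver, brain, striated muscle, germ line), ubiquitous genes, nephron patterning genes, tubular injury genes, immediate early and stress genes, and genes known as higher in male or in female mouse kidney.

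Consensus sequences of 22 transcription factors were searched on both strands in the 200 bp around each peak centre and compared with up to 10 permutations of the same letters holding as many CpG dinucleotides. For SP/KLF only 7 such permutations exist. A site was taken as footprinted where a footprint covered at least 50% of it. No p-value was computed for motifs, since peaks of a library are not replicates. Whether a consensus exceeded all of its permutations is given in its place.

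The groups, tests, gene lists, consensus sequences and most alternatives were chosen before the data were examined. Genes were named by a rule fixed at the same time. From each list of a kidney cell type or of a tissue that dissection could carry along, the rule takes the 2 members with the highest mean promoter signal and the alphabetically first member with no promoter peak in either library. From every other list it takes the member with the highest promoter signal. Some genes that the rule takes are not reported here. It adds Xist and up to 5 list genes in each direction with a promoter peak in only 1 library. Alternatives covered the choice of list, the upper 50% of peaks by signal, promoter windows of 500 bp and 2 kb, flanks of 5 kb and 50 kb, a 50% reciprocal overlap, motif windows of 100 bp, distal peaks alone and each library alone. A signal threshold of 0.193, the trough between the 2 modes of replicate 2's signal distribution, and random lists matched on promoter CpG content were added after the data were seen.

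Intervals are 95% Wilson intervals unless named otherwise (for a motif ratio, that of the share divided by the permuted mean, and for masked bases, 1000 bootstrap resamples of peaks) and cover counting error only. Values over both libraries are the mean ± SD (n = 2). The procedures were tested on simulated data. A planted peak overlap of 60.2% was recovered as 60.1%, and a planted motif share of 9.99% as 10.1%. In the promoter test, 97.8% of lists planted as lower and 0.5% of unchanged lists were called. Those lists were planted far below other genes, so this says little about smaller shifts. The distal test was run on plants of another size, so its sensitivity cannot be compared with that of the promoter test. It called 45% of lists planted at 2.5 times the density of other genes, 5% of lists planted at 0.4 times, and 0% of unchanged lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Signal tracks and alignments were not used here, and hybrid alleles were not separated.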

Results

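Accessible chromatin was mapped in kidney tissue of 2 female B6CASTF1/J mice, 1 DNase-seq library per animal. The stricter list held 110841 peaks in replicate 1 and 242852 in replicate 2, a ratio of 2.19 (176846 ± 93346, SD, n = 2). These peaks covered 22.6 Mb (0.853% of the sequenced genome) in replicate 1 and 46.8 Mb (1.77%) in replicate 2, with median widths of 199 bp and 180 bp. The libraries held 505133 and 963461 footprints, of which 68.3% and 63.5% lay in peaks of their own library. The signal distribution of replicate 2 had a mode at low signal, around 0.0811, that replicate 1 lacked, besides one around 0.459. Below the trough at a signal of 0.193 lay 90816 peaks of replicate 2 (37.4%) and 1588 of replicate 1 (1.43%). Above it the libraries held 152036 and 109253 peaks, a ratio of 1.39.

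**Figure D1:**
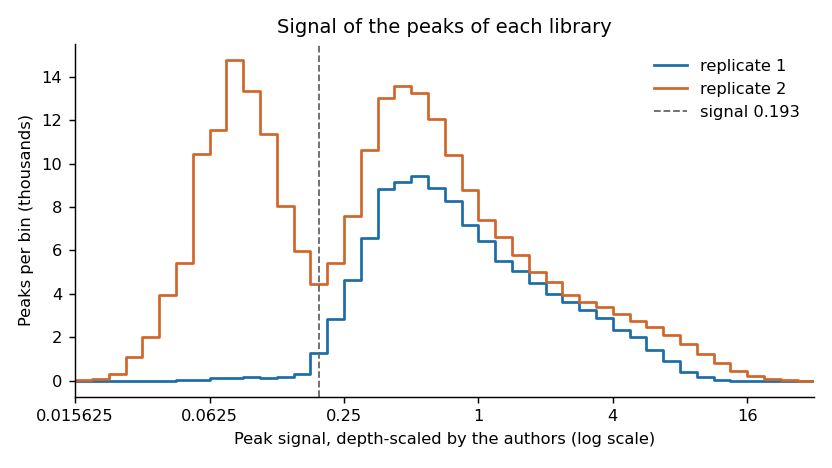
Number of peaks (per bin of log2 signal, divided by 1000, vertical axis) against peak signal, depth-scaled by the authors (log axis), for replicate 1 (blue) and replicate 2 (orange). Replicate 2 has modes near 0.459 and 0.0811, the latter left of the dashed line at 0.193, where replicate 1 has few peaks.

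Markers of the proximal tubule, the thick ascending limb, the distal convoluted and connecting tubule and principal cells had promoter peaks at 75% to 93.3% of their genes. Of 21938 protein-coding genes, 61.9% (95% interval 61.3 to 62.6) had a promoter peak in replicate 1 and 65.9% (65.3 to 66.5) in replicate 2, and 13497 had one in both. Markers of the proximal tubule, the segment that recovers most filtered solutes, had promoter peaks at 20 and 22 of 25 genes (84.0% ± 5.66, SD, n = 2). Markers of the thick ascending limb had them at 13 and 14 of 15 genes, those of the distal convoluted and connecting tubule at 12 and 13 of 14, and those of collecting duct principal cells at 9 and 11 of 12. None of these lists passed Fisher's exact test against all other genes in both libraries (adjusted p = 0.117 and 0.0555 for the proximal tubule, 0.117 and 0.0688 for the thick ascending limb, 0.158 and 0.0803 for the distal convoluted and connecting tubule, 0.606 and 0.107 for principal cells). With a 2 kb window the proximal tubule list was called higher, at 23 of 25 genes in each library (adjusted p = 0.0135 and 0.0427, Fisher's exact test), and with the looser list the thick ascending limb was, at 15 of 15 in each (0.0127 and 0.0285). In the upper 50% of peaks by signal, replicate 1 had promoter peaks at 6 of 14 genes of the distal convoluted and connecting tubule and 5 of 12 of principal cells (42.9% and 41.7%), below the 54.3% of other genes.

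Promoters rich in CpG are open in most tissues, and the lists differ in CpG content. Against random lists matched on promoter CpG ratio, a comparison added after the data were seen, the median random list had a promoter peak at 44% and 52% of genes for the proximal tubule. There 3 lists were called higher, the proximal tubule (adjusted permutation p = 0.0046 in both libraries), the thick ascending limb (0.0046 and 0.0069) and the distal convoluted and connecting tubule (0.0276 and 0.0115). Principal cells (0.22 and 0.0158), endothelial markers (0.0907 and 0.0236) and stromal and mural markers (1 and 0.0153) passed as higher in replicate 2 alone, as did genes known as higher in female kidney (0.079 and 0.012), while neuronal genes passed as lower in replicate 1 alone (0.0138 and 0.139).

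In the proximal tubule list, Pck1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, had a promoter signal of 4.04 ± 0.660 (SD, n = 2, peak at 173152861 to 173153140 of chromosome 2 in replicate 1). Egf, the growth factor precursor made in the distal nephron (2.87 ± 1.78, chromosome 3, 129755361 to 129755540), and Umod, which encodes uromodulin, the main protein of normal urine (2.06 ± 0.0441), led the thick ascending limb. Cnnm2, which acts in magnesium handling (12.6 ± 5.79, chromosome 19, 46761281 to 46761600), and Wnk1, a kinase that controls salt transport (4.83 ± 0.461), led the distal convoluted and connecting tubule. Tfcp2l1, a transcription factor of the collecting duct (5.74 ± 1.22), and Scnn1g, a subunit of the epithelial sodium channel (3.67 ± 0.564), led principal cells. The members without a promoter peak in either library that come first by name were Ggt1, Cldn10, Slc8a1 and Elf5, whose loci held 7 and 15, 12 and 43, 13 and 73, and 9 and 11 distal peaks in replicates 1 and 2. Only the 5′ end of each gene record was searched, so an open alternative promoter of these genes was not counted.

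Cell types other than the segments named so far gave mixed values. Intercalated cells, the acid-base cells of the collecting duct, had promoter peaks at 9 and 10 of 14 genes (adjusted p = 1 and 0.784 by Fisher's exact test), with Rhbg, an ammonium transporter (2.66 ± 0.914), and Kit (0.953 ± 0.308) highest and none at Aqp6. Podocytes, the filtering cells of the glomerulus, had them at 13 and 16 of 18 genes (0.563 and 0.0803). Cd2ap, an adaptor of the slit diaphragm, reached 10.4 ± 2.61 (chromosome 17, 42876621 to 42876820), while Nphs1, which encodes nephrin, had none. Endothelial markers had them at 15 and 17 of 20 genes (0.35 and 0.135), led by Esam (3.13 ± 1.33) and Ehd3 (2.68 ± 0.288), with none at Pecam1. In the upper 50% of peaks by signal, replicate 1 had them at 2 of 14 intercalated cell genes (adjusted p = 0.0105, Fisher's exact test, against 1 in replicate 2) and 8 of 20 endothelial genes.

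Stromal and mural markers differed most between the libraries, with promoter peaks at 7 of 16 genes in replicate 1 and 14 of 16 in replicate 2 (adjusted p = 0.281 and 0.14, Fisher's exact test). Col1a1, a chain of type I collagen (8.46 ± 4.07), and Tagln, a smooth muscle protein gene (3.40 ± 0.860), had the highest signals, and Lum had no promoter peak. The peaks of Col1a1 and Tagln lay more than 500 bp from the gene start. With a 500 bp window the list had promoter peaks at 5 and 13 of 16 genes. The looser list gave promoter peaks at 12 of 16 genes in replicate 1. Of list genes with a promoter peak in replicate 2 alone, the 5 with the highest signal were Tmem52b (1.15), the homeobox gene Hoxa11 (0.997), the endothelial gene Egfl7 (0.892), Pdgfrb, the receptor that marks pericytes (0.823), and Hoxc11 (0.695). The converse held for a single list gene, Dlx1, with a signal of 0.242 in replicate 1. The difference between the libraries has no replicate check.

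Immune markers lay at the other end, with promoter peaks at 2 and 4 of 20 genes (10% and 20%, adjusted p = 5e-05 and 0.000596, Fisher's exact test). C1qc, a complement gene of macrophages, had the highest signal among them (0.586 ± 0.146), followed by Cd8a (0.326 ± 0.119), and C1qa had no promoter peak. The peaks of C1qc and Cd8a lay more than 500 bp from the gene start. With a 500 bp window 0 and 1 of 20 immune genes had a promoter peak. Adrenal genes were also lower, at 2 and 3 of 12 genes (0.0104 and 0.0211). Their open promoters included Chga, the chromogranin A gene of neuroendocrine cells (2.95 ± 1.52), and Star, which acts in steroid synthesis (0.524 ± 0.177), with none at Cyp11a1. Striated muscle genes had peaks at 6 of 19 promoters in each library (0.0393 and 0.0157) and germ line genes at 4 and 5 of 20 (0.00175 and 0.00171). The highest signals in these lists, at Actn3 (6.55 ± 1.25) and the oocyte factor gene Gdf9 (15.3 ± 8.44), came from peaks within 1 kb of the start of another gene, Zdhhc24 and Uqcrq respectively. Ubiquitous genes were higher, at 24 and 25 of 25 genes (0.00144 and 0.000596), led by the ribosomal protein gene Rplp0 (12.5 ± 1.86). With CpG-matched random lists the immune, adrenal, striated muscle and ubiquitous lists were no longer called (adjusted permutation p = 0.264 and 0.505 for immune markers, 0.606 and 0.839 for adrenal, 0.932 and 0.593 for muscle, 0.157 and 0.0358 for ubiquitous genes), and the germ line list remained lower (0.0046 and 0.00767).

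Urothelial, adipocyte, erythroid, hepatocyte and neuronal genes did not pass the promoter test. Urothelial genes had them at 3 of 10 in each library (adjusted p = 0.115 and 0.0791, Fisher's exact test), at Upk2 (5.08 ± 1.79) and Upk1a (2.38 ± 0.339), which encode uroplakins of the urinary tract lining, among others, and not at Krt13. Adipocyte genes had them at 3 and 4 of 10 (0.115 and 0.135), with Cidea (0.915 ± 0.443) and Fabp4 (0.674 ± 0.344) highest and none at Adipoq, the adiponectin gene. Erythroid genes had them at 3 of 10 in each (0.115 and 0.0791), with a signal of 0.949 ± 0.179 at Tal1 and no promoter peak at Alas2. Hepatocyte genes had them at 7 and 8 of 20 (0.0735 and 0.0555), with the protein C gene Proc highest (5.85 ± 2.31). Neuronal genes had them at 8 and 11 of 20 (0.117 and 0.399), with the synaptic gene Snap25 at 2.39 ± 0.689, from a peak more than 500 bp from the gene start. With a 500 bp window neuronal genes had them at 5 and 9 of 20 (adjusted p = 0.00881 and 0.16, Fisher's exact test). The 2 kb window gave 10 and 14 of 20, and the looser list 11 and 16. The urothelial and hepatocyte lists were called lower with a 500 bp window, and the hepatocyte list also with a 2 kb window. The peaks of Upk2 and Upk1a lay more than 500 bp from the gene start, and 1 of 10 urothelial genes had one in the 500 bp window. Adipocyte genes had promoter peaks at 5 and 8 of 10 with the 2 kb window, and at 0 and 3 of 10 in the upper 50% of peaks by signal.

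Genes of nephron patterning, the programme that forms the kidney, had promoter peaks at 18 and 21 of 23 genes (adjusted p = 0.204 and 0.0297, Fisher's exact test), with Pax8 at 5.10 ± 0.652. Immediate early and stress genes had them at 11 of 12 in each library (0.115 and 0.107), with Jun, a subunit of the AP-1 transcription factor, at 13.9 ± 4.02. Tubular injury genes had them at 7 and 8 of 14 (0.528 and 0.601), with Clu at 4.03 ± 0.799. Of genes known as higher in male mouse kidney 4 of 8 had them in each library (0.563 and 0.501), with Cyp4b1 at 3.21 ± 1.55, and of genes known as higher in female kidney 4 and 5 of 5 (0.686 and 0.21), with Abcc3 at 1.26 ± 0.533. In the upper 50% of peaks by signal, replicate 1 had them at 11 of 23 nephron patterning genes, 3 of 14 tubular injury genes, 2 of 8 genes known as higher in male kidney and 1 of 5 known as higher in female kidney.

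**Figure D2:**
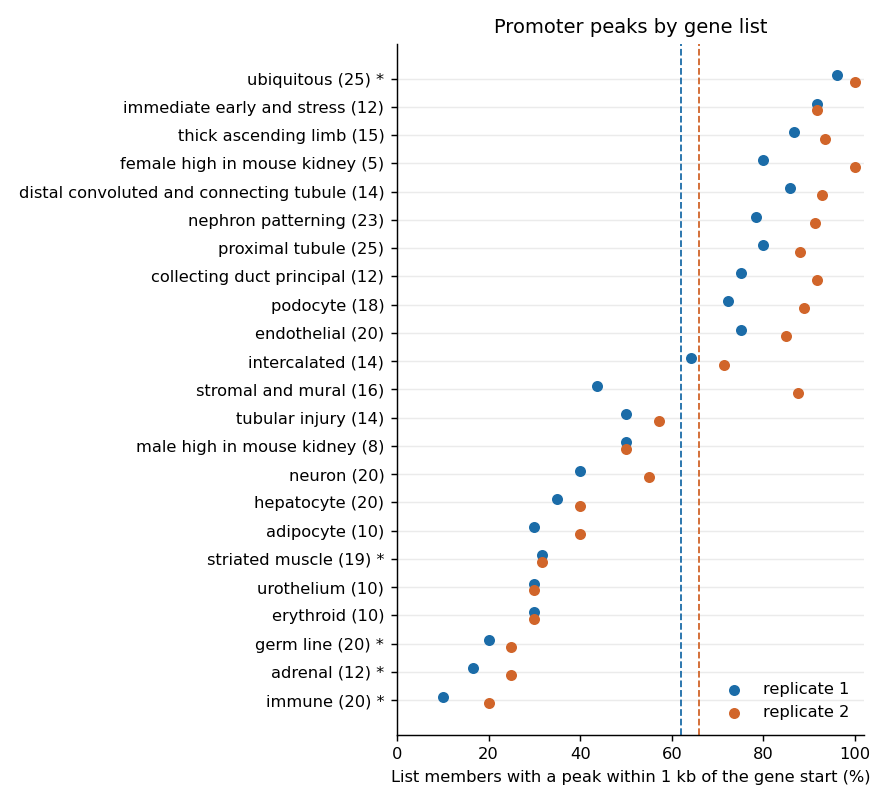
Share of the genes of each list with a peak within 1 kb of the gene start (%, horizontal axis) in replicate 1 (blue) and replicate 2 (orange), with the list's size in brackets and an asterisk where the list was called. Dashed lines give the share over all protein-coding genes, 61.9% and 65.9%. By the mean of both libraries the ubiquitous list stands highest and the immune list lowest.

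Distal peaks were denser at the loci of 3 lists in both libraries. Proximal tubule loci held a median of 1.15 and 2.32 distal peaks per 10 kb in replicates 1 and 2, against 0.461 and 0.869 in random lists of matched locus length (adjusted p = 0.00153 and 0.0023, permutation test). Nephron patterning loci held 1.46 and 2.88 against 0.448 and 0.848 (0.00153 and 0.0023). Immediate early and stress loci held 1.89 and 2.48 against 0.444 and 0.739 (0.00153 and 0.0103), and with 50 kb flanks this list was no longer called (0.00153 and 0.0506). Pck1 held 28 and 31 distal peaks in 46.2 kb, and Pax8 17 and 31 in 95.04 kb. Jun held 6 and 7 in 43.2 kb.

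Thick ascending limb loci passed in replicate 2 alone, with medians of 0.903 and 2.52 against 0.436 and 0.858 (adjusted p = 0.0626 and 0.0092, permutation test). In replicate 2 they did not pass with 50 kb flanks (ratio to random lists 1.80, 0.152) or in the upper 50% of peaks by signal (2.15, 0.11). Principal cell loci passed in replicate 1 alone, with 1.10 and 1.14 against 0.462 and 0.856 (0.0264 and 0.665). There the ratio of replicate 1 was 2.39, and it did not pass with 50 kb flanks (1.34, adjusted permutation p = 0.56), with 5 kb flanks (1.61, 0.478) or in the upper 50% of peaks (1.51, 0.653). The loci of genes known as higher in male kidney held the fewest, 0.176 and 0.174 against 0.512 and 0.941 (0.169 and 0.0561), and those of genes known as higher in female kidney 0.768 and 1.11 against 0.435 and 0.846 (0.48 and 0.818). As ratios to random lists, distal convoluted and connecting tubule loci stood at 1.29 and 1.42, intercalated cell loci at 1.22 and 1.39, podocyte loci at 1.57 and 1.35, endothelial loci at 1.67 and 1.67, stromal and mural loci at 1.64 and 0.982, and immune loci at 1.68 and 1.12. Urothelial loci stood at 1.63 and 0.953, adipocyte loci at 1.51 and 1.27, adrenal loci at 1.08 and 1.52, and erythroid loci at 1.33 and 0.807. Hepatocyte loci stood at 0.851 and 0.716, neuronal loci at 0.782 and 0.769, striated muscle loci at 1.21 and 0.852, and germ line loci at 0.530 and 0.987. Ubiquitous loci stood at 1.55 and 1.62, and tubular injury loci at 1.02 and 1.47. None of these passed the permutation test in either library, and 0 lists were called lower. Several of these ratios depended on the flank. With 5 kb flanks immune loci stood at 0.242 and 0.892 and neuronal loci at 1.29 and 1.04, and with 50 kb flanks hepatocyte loci stood at 1.09 and 1.14 and germ line loci at 1.16 and 1.06, each on the other side of 1 in both libraries. Endothelial loci passed in replicate 2 alone with 5 kb flanks, in the upper 50% of peaks and above a signal of 0.193 (adjusted permutation p = 0.0147, 0.00805 and 0.012).

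**Figure D3:**
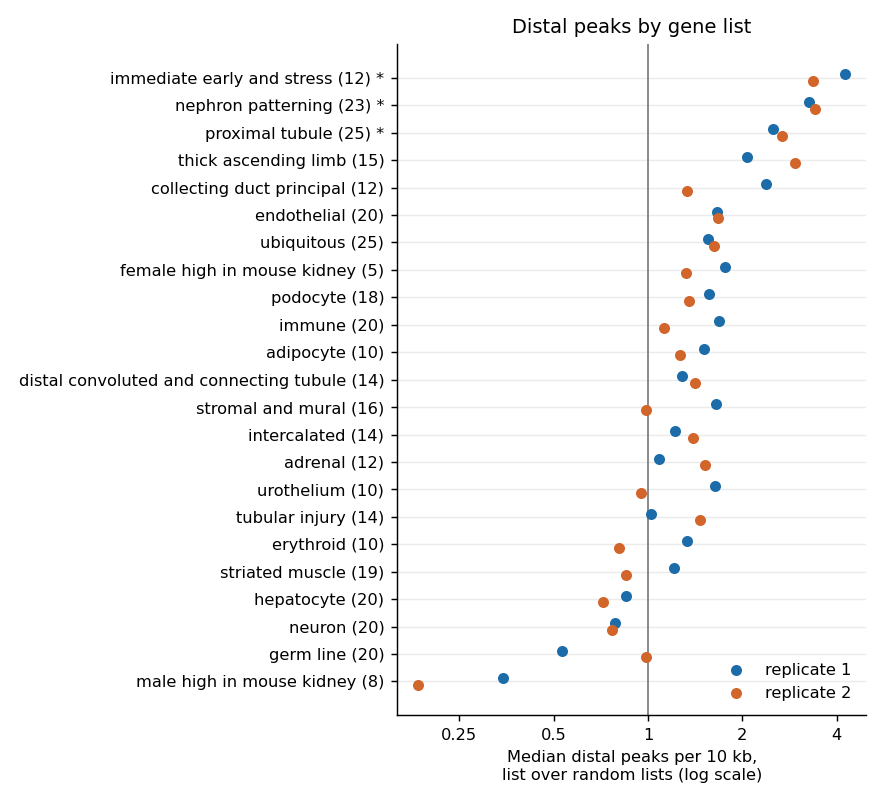
Median number of distal peaks per 10 kb of each list's loci divided by the median of random lists of matched locus length (log axis), for replicate 1 (blue) and replicate 2 (orange), with list sizes in brackets and an asterisk where the list was called. The vertical line marks a ratio of 1. The immediate early and stress and the nephron patterning lists stand highest in both libraries.

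The Egf locus had the widest gap between the libraries among the named genes of the thick ascending limb. Its gene body and 20 kb flanks on chromosome 3 (129657565 to 129775316) held 11 peaks in replicate 1 and 109 in replicate 2, of which 58 lay below a signal of 0.193. The promoter peak was called at the same bases in both, with signals of 1.61 and 4.13.

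**Figure D4:**
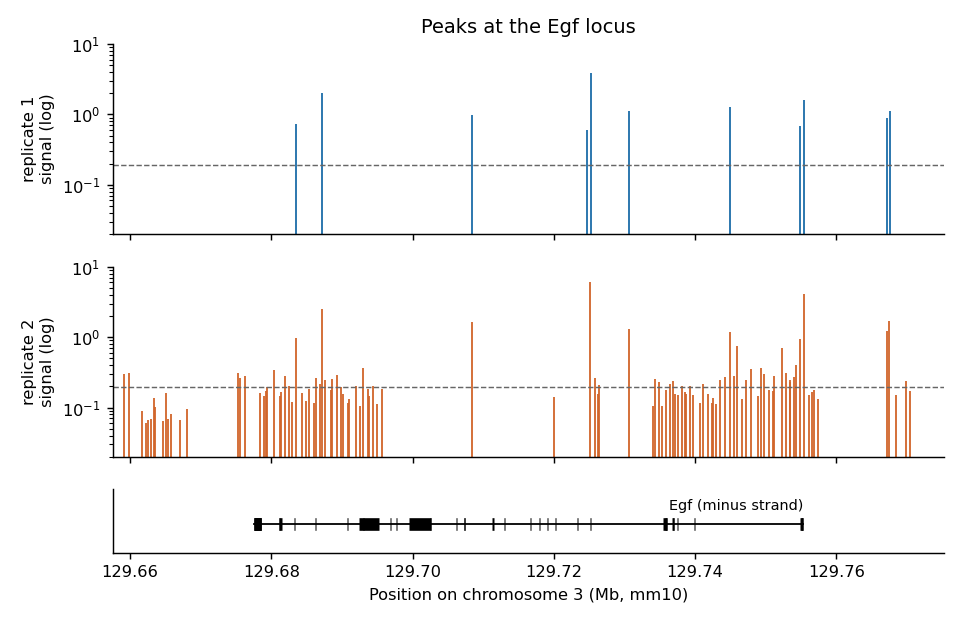
Peaks at the Egf locus on chromosome 3 (position in Mb, mm10) in replicate 1 (upper panel) and replicate 2 (middle panel), each drawn as a line with its signal as height (log axis), above a map of Egf with its exons as boxes. The dashed line marks a signal of 0.193. Replicate 2 has 109 peaks here against 11 in replicate 1.

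Of 22 consensus sequences, 14 occurred more often than in all of their permutations in both libraries, 11 of 16 of kidney or general factors and 3 of 6 of factors of other tissues. The sequence of CTCF, the chromatin loop anchor (CCASYAGRKGGC), was found in 6.07% and 2.83% of peaks, 43.7 and 21.9 times the mean of its permutations. That of HNF1, a factor of tubular epithelium (GTTAATNATTAA), was found 13.9 and 4.33 times as often as its permutations, in 0.147% and 0.0515% of peaks, and that of HNF4, a factor of the proximal tubule, 6.82 and 3.96 times. Above a signal of 0.193 the HNF1 ratio of replicate 2 was 8.88. In 100 bp windows the ratios were 83.4 and 40.9 for CTCF, 30.3 and 6.79 for HNF1, and 267 and 136 for REST. NRF1 reached 11.6 and 10.8 times, USF 9.18 and 7.32, ETS 5.32 and 3.73, SP/KLF 4.70 and 4.21, ESRR, a regulator of oxidative metabolism, 3.08 and 3.54, TEAD 2.43 and 1.94, PAX2/PAX8 1.75 and 1.29, and TFCP2L1 1.37 and 1.42. Among factors of other tissues, REST, which silences neuronal genes outside the nervous system, reached 97.9 and 74.2 times on 285 and 329 sites, RFX 3.76 and 2.42, and the octamer 2.24 and 1.94. The permuted forms had a median of 2 and 4 sites for REST and of 10 and 19 for HNF1, so both ratios are imprecise.

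The remaining 8 sequences did not exceed all of their permutations. AP-1 stood at 1.04 and 0.98 times the permuted mean, NFY at 1.61 and 1.24, GRHL at 0.90 and 0.709, GATA at 0.709 and 0.866, the steroid receptor site at 1.08 and 0.817, MEF2 at 1.01 and 0.720, PU.1 at 1.54 and 1.47, and C/EBP at 0.702 and 0.493. In distal peaks alone, ETS and RFX exceeded all permutations in replicate 1 (2.35 and 2.70 times) and not in replicate 2 (2.00 and 1.87). NFY did so in 100 bp windows in replicate 1 (2.13 times) and not in replicate 2 (1.47).

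Footprints covered the sites of several of these factors more often than permuted sites. Of CTCF sites in peaks, 97.9% and 97.52% were footprinted, against 29.4% and 32.3% of permuted sites. The shares were 94.4% and 94.5% for REST, 92.7% and 94.8% for NRF1, 81.4% and 74.4% for USF, 67.0% and 66.7% for HNF1, and 56.8% and 54.9% for HNF4. Permuted REST sites reached 27.8% and 29.4%, on a median of 2 and 4 sites, and permuted HNF1 sites 28.0% and 11.5%, on 10 and 19. REST exceeded all permutations in replicate 1 alone with an overlap of 1 base, and in replicate 2 alone above a signal of 0.193. For HNF4 the permuted sites reached 20.2% and 17.9%. TFCP2L1 sites were footprinted at 30.9% and 34.7%, below the permuted means of 36.4% and 41.6%. In total, 14 of 22 sequences exceeded all of their permutations in both libraries. Among them were C/EBP (64.2% and 68.6%) and MEF2 (23.8% and 17.3%), which had not exceeded all of theirs in the share of peaks. Above a signal of 0.193 the number was 10, without REST and without ESRR, NFY and PAX2/PAX8, which exceeded theirs in replicate 1 alone.

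**Figure D5:**
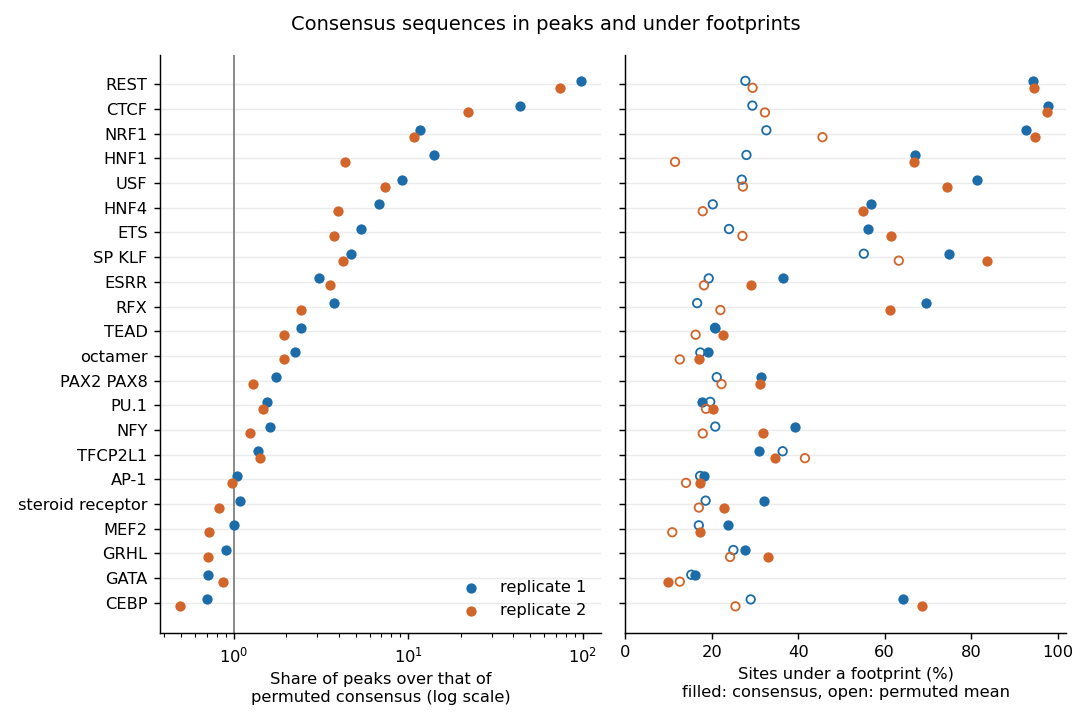
Left, share of peaks holding each consensus sequence divided by the mean share of its permutations (log axis), for replicate 1 (blue) and replicate 2 (orange), with a vertical line at 1. Right, percentage of sites in peaks under a footprint, with filled points for the consensus and open points for the permuted mean. REST and CTCF stand highest on the left, and both are above 90% on the right.

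Peaks lay near gene starts far more often than the genome does. Promoter windows took 20.2% and 11.2% of peaks (15.7% ± 6.38, SD, n = 2) against 1.56% of the genome, exons 6.52% and 6.64% against 3.26%, introns 37.8% and 42.0% against 35.1%, and intergenic sequence 35.5% and 40.1% against 60.1%. Above a signal of 0.193 the promoter share of replicate 2 was 17.2%, and that of replicate 1 was 20.4%. Chromosome 11 had the highest peak density of the autosomes in both libraries, with 69.3 and 126.8 peaks per Mb.

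The labels give both animals as female. Chromosome X held 16.4 and 29.7 peaks per Mb, 0.363 and 0.299 times the autosomal density of 45.1 and 99.3. Chromosome Y held 29 and 78 peaks, or 0.329 and 0.885 per Mb. Xist, the RNA that coats the inactive X chromosome, had a promoter peak in both libraries (2.96 ± 0.396, X, 103484161 to 103484340). That peak lay upstream of the 5′ end of the gene record, at 103483254, near the edge of the 1 kb window.

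The peaks of replicate 1 were largely found again in replicate 2. Of its 110841 peaks, 89.3% (95% interval 89.2 to 89.5) overlapped a peak of replicate 2, against 3.53% after shifting. Of the peaks of replicate 2, 41.1% (40.9 to 41.3) overlapped a peak of replicate 1, against 1.66%, and above a signal of 0.193 the share was 65.2%. With the same number of highest-signal peaks in both lists the shares were 79.0% and 79.4%. Footprints recurred less often, at 68.3% and 32.9% of each library's total, and at 79.6% and 61.3% of those inside peaks of both libraries. In the latter, shifting gave 0.492% and 0.4%. Requiring 50% of both footprints lowered the shares over all footprints to 42.1% and 22.1%.

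Over 87126 peaks matched at 50% reciprocal overlap, the log2 signals of the libraries correlated with a Pearson r of 0.943 and a Spearman rho of 0.930 across peaks, which are not independent replicates. The median log2 ratio of replicate 2 over replicate 1 was 0.44, at 0.47 for promoter peaks and 0.43 for distal peaks. Replicate 2 had 143074 peaks with no partner in replicate 1, at a median signal of 0.118 against 1.10 for shared peaks. Of these, 4.32% lay at promoters and 45.2% in introns, against 21.1% and 37.5% of shared peaks. Replicate 1 had 11808 peaks without a partner, of which 13.8% lay at promoters.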

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

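The settings that use a signal threshold of 0.193 or CpG-matched random lists were chosen after the data were seen, and the other settings were planned. No paired analysis was possible because the labels give only 1 group. Of 1113 values under an alternative setting, 913 kept their call or stayed within a limit set for their kind of value. The limit was the spread between libraries for mean values, the 95% interval for shared percentages and a fixed ratio for counts. The values include each library alone, which by construction lies within the SD of 2 libraries. That setting also cannot end a list call, which needs both libraries, so its unchanged values are no evidence of stability. A further 184 values moved past their limit. Gene lists gained a call in 11 values and lost it in 5, and 0 called values turned in direction. Distal ratios of lists that were not called did turn, in both libraries for immune and neuronal loci with 5 kb flanks, hepatocyte and germ line loci with 50 kb flanks and striated muscle loci in the upper 50% of peaks. In 1 library they turned under at least 1 setting for intercalated cell, podocyte, stromal and mural, urothelial, adrenal, erythroid and tubular injury loci and for genes known as higher in female kidney. Motifs carry no test, but in distal peaks ETS and RFX exceeded all permutations in replicate 1 alone, as did NFY in 100 bp windows. Under footprints with 1 base of overlap, PAX2/PAX8 did in replicate 2 alone and REST in replicate 1 alone, while the steroid receptor site newly did in both. Of motifs that did not exceed theirs, GRHL, MEF2 and the steroid receptor site crossed a mean ratio of 1 in 100 bp windows, as MEF2 did above the signal threshold and PU.1 under footprints with 1 base of overlap. The looser list gave 168100 peaks in replicate 1, shared peaks of 86.4% and 40.8%, and 2 lists with a higher promoter share in place of 1, the second being the thick ascending limb. The upper 50% of peaks by signal left 55641 and 121743 peaks, of which 99.0% and 75.6% were shared with all peaks of the other library. It gave promoter peaks at 58.4% of genes and shifted the mean peak positions to 23.5% promoter, 6.78% exon and 32.0% intergenic. For chromosome X and Y peaks, X over autosomes then stood at 0.275, against 0.331 for all peaks. For chromosome X and Y peaks, Y over autosomes stood at 0.00327, against 0.0081. Above the signal threshold replicate 2 kept 152036 peaks, 1.39 times replicate 1, and the shared shares were 90.01% and 65.2% for peaks, 79.5% and 79.9% for equal numbers, and 72.2% and 44.3% for footprints. The exon share there was 6.84%, the Y ratio 0.00491, and 52955 peaks of replicate 2 had no partner. With 50% of both features required, 78.8% and 35.97% of peaks, 71.7% and 71.7% of equal-number peaks, and 42.1% and 22.1% of footprints were shared, a stricter demand by construction. Footprints inside peaks of both libraries were shared at 79.6% and 61.3%. Equal numbers of peaks left 23249 and 22811 without a partner. The 2 kb promoter window gave 67.2% of genes and 2 lists called higher, the second being the proximal tubule, and the 500 bp window an exon share of 7.77%. CpG matching gave 3 lists higher and 1 lower, of which 1 was among the 5 called in the main test. With each library alone, 1 to 2 lists were higher at promoters, the second being nephron patterning in replicate 2. The promoter share lay between 61.9% and 65.9%, 4 lists were called higher at distal sites in either library (the fourth being principal cells in replicate 1 and the thick ascending limb in replicate 2, neither of which passed under every setting), and 14 motifs exceeded their permutations in peaks in each. The 3 distal calls remained under the 5 kb flank, the upper 50% of peaks and the signal threshold, and the 50 kb flank ended that of immediate early and stress genes. Where a value moved, the cause was not tested unless the setting itself gives it. Whether depth sets the number of footprints per library was not tested. The distal test, which recovered 45% of lists planted at 2.5 times and 5% at 0.4 times the usual density, says little about the lists it did not call.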

Other observations

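The gene families and the densest loci below, and the tests that overlap replicate 2's peaks with replicate 1's looser peaks, were chosen only after the data were seen. Families of chemosensory genes stood apart from the solute carriers. Among 42 families grouped by symbol, 10 had more promoter peaks than other genes and 10 had fewer in both libraries (Fisher's exact test with Benjamini-Hochberg adjustment over the families). The families were not compared with CpG-matched random lists, which ended most promoter calls of the gene lists. Olfactory receptor genes (Olfr) had promoter peaks at 9 and 21 of 1135 genes in replicates 1 and 2, vomeronasal receptors (Vmn1r) at 1 and 2 of 209, and Vmn2r at 0 of 120 in each. Solute carriers (Slc) had them at 283 and 305 of 385 (adjusted p = 6.17e-06 and 5.09e-08, Fisher's exact test), their mitochondrial branch Slc25 at 40 and 42 of 47 (0.00179 and 0.000743), and subunits of the vacuolar proton pump (Atp6v) at 20 and 21 of 23 (0.0338 and 0.0155). Mitochondrial ribosomal proteins (Mrp) had them at 76 and 77 of 78 and respiratory complex I subunits (Nduf) at 45 of 46 in each, while cytochrome P450 genes (Cyp) had fewer, at 43 and 47 of 107 (1.63e-05 and 1.41e-05). Members of a family often lie side by side and share regions, so they are not independent.

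Distal peaks set other families apart. Hox loci held a median of 2.58 and 4.85 distal peaks per 10 kb, against 0.438 and 0.686 in random lists (adjusted permutation p = 0.000933 and 0.00105), Klf loci 1.10 and 1.88 against 0.430 and 0.819 (0.00336 and 0.0297), and Slc loci 0.658 and 1.25 against 0.464 and 0.90 (0.000933 and 0.00105). Zinc finger genes (Zfp) had more promoter peaks than other genes, at 330 and 337 of 397, but fewer distal peaks, at 0.227 and 0.552 against 0.481 and 0.888 (0.000933 and 0.00105). Protocadherins (Pcdh) likewise held few distal peaks, 0.0899 and 0.214 against 0.411 and 0.828. Peaks near gene starts were left out while the full locus length was kept. That lowers the density where gene starts lie close together, by an amount not determined here. Above a signal of 0.193, where the median protein-coding locus held 0.439 and 0.616 distal peaks per 10 kb, the densest loci included Pou3f3, a distal nephron patterning gene, with 9.28 and 7.38, Hoxa10 with 6.44 and 9.87, Gabarapl1 with 8.95 and 7.32, and Txnip with 7.06 and 7.97. Atp1b1, a sodium pump subunit gene (6.37 and 6.2), also stood far above that median. Slc25 loci were called higher over the full list, with 0.757 and 1.42 against 0.460 and 0.882 (adjusted permutation p = 0.0239 and 0.0287). Above that signal they were not called, with 0.757 and 1.00 against 0.458 and 0.666 (0.0213 and 0.0721), and Slc22 loci were, with 0.854 and 1.12 against 0.443 and 0.645 (0.00687 and 0.0437).

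Replicate 2 had 90355 peaks below a signal of 0.193 that replicate 1 lacked. The median gap between its peaks below that signal was 580 bp, with 71.6% of gaps under 1 kb, and 50% of these peaks fell in 1046 of 27268 windows of 100 kb (3.84%), the densest of which lies in Xpr1 (chromosome 1, 155300001 to 155400000, 133 such peaks). Repeats as the whole source are argued against, since most bases of the 90355 peaks were not soft-masked. The soft-masked share was 23.7% (95% bootstrap interval 23.5 to 23.9), below the 36.4% of the genome. It was above the 10.9% of replicate 2's peaks above that signal and the 14.0% of those among them that replicate 1 lacked. Since these sets also fell below the genome share, that comparison cannot test a partial role of repeats. The CTCF sequence occurred 0.910 times as often as its permutations (95% interval 0.726 to 1.14) and 6.55 times as often in the weakest 10% of peaks above the threshold. Calls at the background level of cuts would give that. The second set was not limited to peaks that replicate 1 lacked, however, and other motifs differed from CTCF. In replicate 2, ESRR stood at 3.54 times its permutations over all peaks and 3.46 above that signal, and TFCP2L1 at 1.42 and 1.39. Leaving out peaks below that signal thus did not raise these ratios. It raised those of CTCF (21.9 and 29.4) and of the other sequences that exceeded all of their permutations. The motifs therefore do not settle the point. An even background would not gather in so few windows, so what set those regions apart stays open. Weak accessible sites cannot be told apart from such calls, since 0.767% of these peaks overlapped a looser peak of replicate 1 outside its stricter list, against 0.761% after shifting, but 92.4% of them lay below the tenth percentile of signal among those looser peaks, and no biological explanation was tested.

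Replicate 2 also had more peaks above that signal, including 52719 that replicate 1 lacked, at a median signal of 0.404. Of these, 42.4% (95% interval 41.9 to 42.8) overlapped a looser peak of replicate 1 outside its stricter list, against at most 0.825% in 100 shifts. Greater depth of replicate 2 would give this, with sites just under the threshold in replicate 1 passing it in replicate 2. The test cannot tell depth from a higher signal at peaks. Depth-scaled signals of matched peaks were higher in replicate 2, by a median log2 ratio of 0.44. The peaks without such a partner, and a difference between the animals, stay open.

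The 20 highest-signal peaks of replicate 1 were led by a site at 143482981 to 143483140 of chromosome X (signal 67.2, and 127 in replicate 2), a site in a ribosomal RNA gene on chromosome 17 (39846781 to 39846900, 45.8) and a site in Lars2 on chromosome 9 (123461921 to 123462080, 41.4). Of the 20, 13 held a 36-base word found in more than 1 place of the assembly, against 2 of 20 peaks drawn at random from the same list, which is in line with reads from near-identical copies. No word of the 20 peaks was found in the mitochondrial genome. Some peaks without a repeated word lay close to a gene start, at 7 bp for Hjurp, 145 bp for Nup107 and 191 bp for Acin1. Others did not, such as that in Cers5 on chromosome 15 (99735641 to 99735920, 29.9). The high signal of the peaks without a repeated word stays unexplained, and no biological explanation was tested.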
